A study of Drosophila melanogaster with 3 samples.

How the data were processed

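Chromatin immunoprecipitation with sequencing was carried out on whole Drosophila melanogaster embryos collected 0 to 24 h after egg laying, per the labels. The flies carried a transgene for CG14860 fused to enhanced green fluorescent protein, and the fusion protein was precipitated with an antibody to the fluorescent protein. Chromatin was sheared by sonication to fragments of 200 to 800 bp. The labels describe 3 biological replicates of 1 group. The control libraries were not analysed here, so no peak could be set against an untagged or mock precipitation.

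The deposited files were peak lists on dm6. Per the file records, each list was derived from filtered alignments of the embryos and a shared control alignment; the aligner, the peak caller, the read length and the sequencing depth are not given in the sources used here. For each replicate there was a ranked list and a thresholded list, and for the series there were 4 of each. The records of the series lists name the alignments of all 3 replicates, but not which replicates or pooled sets each list compares. Each peak carries a signal value deposited by the authors, whose normalization is not stated; it was used to describe, rank and filter peaks within a list and was never compared between lists. Each peak also has a score deposited by the authors, which is the scaled irreproducible discovery rate (IDR) and reaches 1000 at most. The ranked lists add the −log10 of the global IDR, as deposited by the authors. Tested on the files, each thresholded list was held in full by 1 ranked list, and its peaks had a −log10 of at least 2, which is an IDR of 0.01. The ranked lists of the series also hold 32 columns with the values of the compared sets, which could not be assigned to replicates and were not used.

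The thresholded series list that its name marks as conservative was taken as the main list. Peaks on the arms 2L, 2R, 3L, 3R, 4, X and Y were used, 2827 of 2884, with the 143560 peaks below the threshold in the parent ranked list as background. Genes, transcription start sites (TSSs) and transposable elements came from Ensembl release 115, and sequence from the RefSeq assembly of the same build. A summit within 500 bp of a TSS was called a promoter summit, whatever else it overlapped. Other summits were classed in the order 5′ UTR, coding exon, 3′ UTR, noncoding exon, intron and intergenic. Location and arm shares were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 6 classes and 7 arms. Odds ratios had 0.5 added to each cell, and their 95% intervals were Woolf's. Shares of peaks have exact Clopper-Pearson intervals, which cover counting error only, and a count of 0 is given the share that 3 peaks would make. The 26 gene lists were tested against the 14279 genes with any ranked summit within 500 bp of a TSS. The 26 consensus sequences were sought on both strands within 100 bp of summits and tested against 12159 background peaks matched on promoter class and on GC content in bins of 5 percentage points. Up to 5 background peaks were drawn per peak, and 4.3 on average were found. The 20 leading 8-mers of arms 2L and 2R were tested on 3L, 3R, 4 and X. Overlap of replicates, of at least 1 bp, was set against 1000 circular shifts of the shorter list in a one-sided permutation test.

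Each replicate's own thresholded list was run through the same steps against its own ranked list, and the mean ± SD over these 3 lists is given as the replicate error. Lists, consensus sequences, tests and most alternatives were fixed before the data were examined. Text names the 25 peaks with the highest signal value, each with the gene of the nearest TSS, CG14860, and up to 4 genes per list by signal value. The alternatives were another peak list, the 500 strongest peaks, other windows, backgrounds and definitions of overlap, and leaving out each replicate. For location, arms, gene lists and sequences, leaving out a replicate meant keeping the main-list peaks found in both other replicate lists, which were 1668, 1783 and 1587 peaks without replicates 1, 2 and 3. The replicate and this filter change together, so their effects were not separated. Noncoding exons were counted as a location but stood outside the adjusted tests.

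The tests were run on simulated peak sets. All 5 planted effects were recovered. In 5 random draws of 2827 ranked peaks, no location class, arm, gene list, consensus sequence or 8-mer was called. In 100 further draws, at least 1 of the 26 gene lists was called in 9, and in 100 draws with the promoter share of the main list in 24. The gene list test therefore calls more often than its nominal rate, and a test against promoter-matched draws was added after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.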

Results

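CG14860-eGFP was mapped in chromatin of 0 to 24 h embryos in 3 biological replicates of 1 group. The thresholded lists held 2039 peaks in replicate 1, 1955 in replicate 2 and 2594 in replicate 3, 2196 ± 347 (SD, n = 3). The ranked lists behind them held 129676, 133689 and 68167 peaks. Read depth is unknown. The main list held 2884 peaks with a median width of 450 bp.

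The question within this design is how far the replicates found the same sites. Replicates 1 and 2 shared 1529 of the 1929 peaks on the arms in the shorter list, 79.3%. Replicates 1 and 3 shared 1745 of 2007, 86.9%, and replicates 2 and 3 shared 1631 of 1929, 84.6%. Circular shifts gave means of 0.941%, 1.21% and 1.16%. The adjusted p of the one-sided permutation test was 0.001 for every pair, the smallest that 1000 shifts can give. Shifted peaks do not stay at promoters, so this p does not separate finding the same sites from a shared preference for promoters. The Jaccard index by base pairs was 0.475, 0.475 and 0.418. The sources do not state which replicates the main list compares. Of its 2827 peaks on the arms, 1509 were found in all 3 replicate lists, 53.4% (95% interval 51.5 to 55.2%), and 436 in none, 15.4% (14.1 to 16.8%). Those in all 3 had a median signal value of 306, against 103 for those in none. Where an overlap of 50% of both peaks was required, 34.6% were found in all 3. Among the 500 strongest peaks 495 were found in all 3, 99.0% (97.7 to 99.7%). For the 1509 peaks the SD of the 3 replicate summits had a median of 18.7 bp (bootstrap interval 17.7 to 19.7 bp).

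The peaks lay at promoters. In the main list 2340 of 2827 summits, 82.8%, were within 500 bp of an annotated TSS, against 13.7% of below-threshold peaks. The replicate lists gave 87.4% ± 0.160 (SD, n = 3), against 15.5% ± 1.84 in their backgrounds. The odds ratio was 30.2 (27.4 to 33.4), and the p of Fisher's exact test was below 2.23e-308, the smallest number that could be represented. Introns held 8.28% of summits against 37.5% in the background, intergenic sequence 6.08% against 24.7%, and coding exons 1.31% against 19.7%. Summits in 5′ UTRs and 3′ UTRs were also fewer, at 0.0707% against 0.907% and 1.20% against 2.66%. All 5 of these classes passed adjustment, the largest adjusted exact p being 1.5e-07. Each summit had a single class and promoter was assigned first, so a higher promoter share lowers the other shares. These 5 tests are therefore not separate findings, and shares among summits away from promoters were not tested. The promoter share went from 68.6% in the quintile of peaks with the lowest signal values to 96.6% in the highest.

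**Figure D1:**
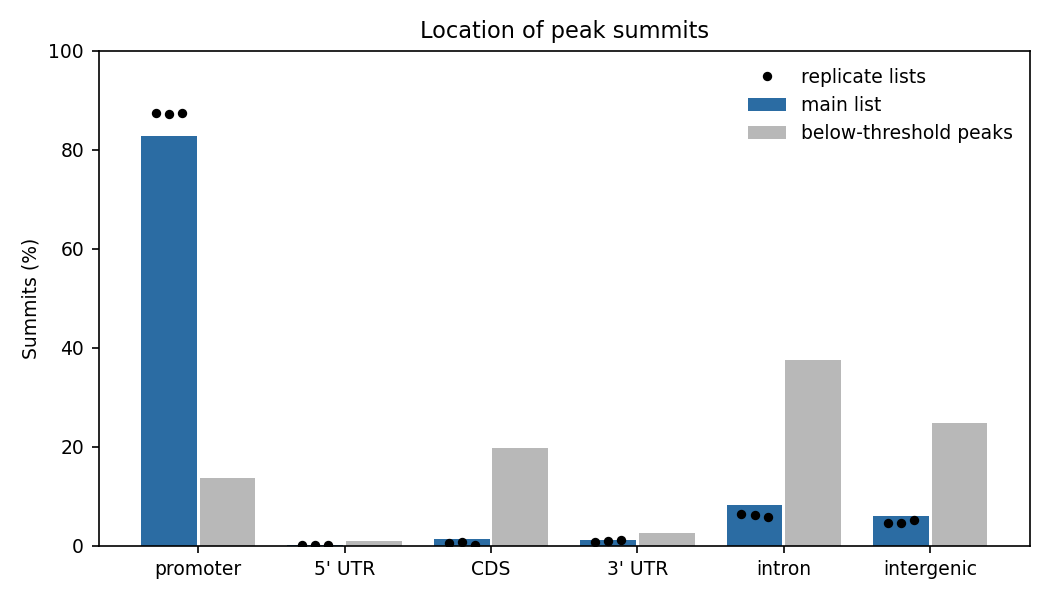
Share of peak summits in each location class, in percent, for the main list (blue bars), the below-threshold peaks (grey bars) and each of the 3 replicate lists (points). Promoters held 82.8% of main-list summits and 13.7% of below-threshold summits.

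The strongest peak lay between MESK2 and TAF1C-like on 2R, from 21501722 to 21502184 on dm6, 92 bp upstream of the MESK2 TSS. Its signal value of 2022 was the highest in the main list, it ranked first in every replicate list, and its replicate summits had an SD of 7.81 bp. The next was at Rpn6, a subunit of the proteasome lid, and ave (2R, 14752172 to 14752588, signal value 1644). It was followed by the promoters of Mic26-27 and CG5916 (3R, 16146618 to 16147119, 1478), Ube3a, a ubiquitin ligase, and CG7600 (3L, 11210419 to 11210870, 1451), and RhoGAP93B (3R, 21097725 to 21098115, 1446). RpL32, a protein of the large ribosomal subunit, had a peak 74 bp upstream of its TSS (3R, 30046073 to 30046464, 1340). Capr (3L, 18673056 to 18673440) had a signal value of 1289, and CG11857 (3R, 25258640 to 25258981) of 1183. The peak at milt, which encodes an adaptor for mitochondrial transport, lay 141 bp upstream of the TSS (2L, 7048966 to 7049296, 1148). The adducin gene hts shared a peak with CalpA (2R, 19424823 to 19425160, 1118). The other promoters among the 25 strongest peaks were those of CG13766, CG8613, EndoGI, Creld, Pp2A-29B, CtsF, Hacl, Ptpmeg, mi, Jwa, mtSSB, Daxx, Fit2 and jagn, with signal values from 938 to 1112.

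Of the 25, 24 were at promoters and all 25 were found in all 3 replicates, with SDs of the summit from 1 to 32.7 bp. The exception in location was a peak in an intron of org-1, a T-box transcription factor gene (X, 8452180 to 8452569, signal value 1401). It lay 2501 bp from the nearest TSS and ranked 2, 2 and 28 in replicates 1, 2 and 3. The tagged gene itself, CG14860 (FBgn0038273, 3R, 14894784 to 14896446), had no main-list summit within 500 bp of its TSS. The nearest summit was 3651 bp from its TSS, at Nup93-2 and CG3817 (3R, 14898210 to 14898659, 230).

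Genes for tRNAs, splicing factors, insulator proteins and cytosolic ribosomal proteins had a peak more often than other genes, and genes for chemoreceptors and cuticle proteins less often. Of 14279 background genes 3107, 21.8%, had a main-list summit within 500 bp of a TSS. The list tests called 10 of the 26 gene lists higher and 5 lower at an adjusted exact p under 0.05 by Fisher's exact test. That test made at least 1 call in 24 of 100 simulated draws with the promoter share of the main list, and 14 of the 15 calls remained against promoter-matched draws. Where a replicate is left out below, only the 1587 to 1783 peaks found in both other replicate lists were kept, so a lost call can come from the filter as well as from the replicate. Among tRNA genes 166 of 282 had a peak, 58.9% (odds ratio 5.37, 4.22 to 6.83, adjusted exact p = 6.8e-41), and the replicate lists gave 54.4% ± 4.60 (SD, n = 3). The highest signal values among them were 582 at tRNA:Glu-CTC-2-3 (3L, 22847621 to 22847874) and 566 at tRNA:Gly-TCC-1-2 (3R, 7130869 to 7131092), followed by tRNA:Leu-AAG-1-3 and tRNA:Pro-TGG-1-1. Among the 500 strongest peaks the tRNA odds ratio was 1.82 (adjusted exact p = 0.0496). Splicing and RNA processing genes had a peak in 19 of 26, 73.1% (odds ratio 9.40, adjusted exact p = 1.71e-07), among them SF2, Sf3b1 and SmD3. The replicate lists gave a lower share, 51.9% ± 5.36 (SD, n = 3). The splicing odds ratio was 4.36, 3.43 and 3.37 without replicates 1, 2 and 3, and 5.79 among the 500 strongest peaks. Promoter-matched draws gave a mean of 4.07 splicing genes with a peak, against 19 observed. Of the insulator and architectural protein genes 10 of 15, 66.7%, had one (odds ratio 6.88, adjusted exact p = 0.000879). They included BEAF-32 (2R, 14771548 to 14771690, signal value 352) and Dref (2L, 9966905 to 9967354, 336), whose protein binds the DNA replication-related element, and mod(mdg4) and pita. The Dref summit also lay within 500 bp of a TSS of RpL13. The insulator odds ratio was 11.2 without replicate 1 and 4.55 with a window of 250 bp, and among the 500 strongest peaks the list was not higher, at 0.584. In promoter-matched draws the mean was 3.22 insulator genes with a peak, against 10 observed. The ratio of these counts, with a constant added to both, was 2.82 and is not on the scale of the odds ratios.

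Cytosolic ribosomal protein genes had a peak in 40 of 78, 51.3% (replicate lists 40.7% ± 3.81, odds ratio 3.82, adjusted exact p = 1.19e-07), with RpL32, RpS7, RpS2 and RpL26 highest. Cell cycle genes had one in 14 of 31 (odds ratio 2.99), led by CycB, aurA, Mcm5 and BubR1, and translation factors in 17 of 43 (2.38), led by eIF3c, eIF3f1, eIF3a and eIF2gamma. The 6 lists from tRNA genes to translation factors were also called whichever replicate was left out. Among the 500 strongest peaks only tRNA, splicing, cytosolic ribosomal protein, translation factor and chemoreceptor genes were called, and cell cycle genes had an adjusted exact p of 0.251. The odds ratio of translation factors was 4.38 there, and that of cell cycle genes 6.09 with the largest other list. With a promoter window of 250 bp, translation factors had an adjusted exact p of 0.102. Proteasome genes had a peak in 20 of 42 (odds ratio 3.29), with Rpn6, Prosalpha7, Prosbeta2 and Rpn10 highest, but the adjusted exact p was 0.28 without replicate 1 and 0.145 without replicate 3, at odds ratios of 1.66 and 2.01. Mitochondrial ribosomal proteins (27 of 67, led by mRpL4, mRpL39, mRpL42 and mRpL17) had an odds ratio of 2.45, and oxidative phosphorylation (27 of 71, led by ND-B14.5A, ND-SGDH, UQCR-14 and COX7A) of 2.23. Their adjusted exact p was 0.0765 and 0.0648 without replicate 2, and 0.0809 and 0.0675 without replicate 3. The Polycomb and Trithorax group had a peak in 10 of 23 (2.80), led by kis, Asx, Scm and Utx, with an adjusted exact p of 0.25 without replicate 1 and 0.197 without replicate 3, 0.168 with the 250 bp window and 0.0524 with the largest other list. Under circular shifts, the ratio of genes with a peak to the mean drawn was 8.86 to 27.2 in the 10 lists called higher. A constant was added to both counts, so these values are not plain multiples of the mean.

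Chemoreceptor genes had a peak in 2 of 136 (odds ratio 0.0661, adjusted exact p = 4.15e-11), Ir31a and Ir76a, and cuticle protein genes in 1 of 87 (0.0619, adjusted exact p = 1.53e-07), Cpr73D. In each of these 3 cases the summit also lay within 500 bp of a TSS of another gene. Both lists were also called whichever replicate was left out, but cuticle proteins had an adjusted exact p of 0.0639 among the 500 strongest peaks. The cuticle odds ratio ranged from 0.0305 to 0.0351 without a replicate, and it was 0.0176 with the largest other list and 0.117 with a window of 1000 bp. Promoter-matched draws gave means of 22.1 chemoreceptor and 15.2 cuticle genes with a peak, against 2 and 1 observed. Under circular shifts, in a test for higher counts alone, the means drawn were 3.81 and 2.39. None of 21 dorsoventral patterning genes had a peak (adjusted exact p = 0.0268), and of 26 neural genes only loco did (adjusted exact p = 0.0499). The dorsoventral call had an adjusted exact p of 0.145, 0.11 and 0.18 without replicates 1, 2 and 3, and the neural call of 0.25, 0.167 and 0.323, with an odds ratio of up to 0.144 and 0.364. Under circular shifts the means drawn were 0.73 dorsoventral and 1.03 neural genes, against 0 and 1 observed. The neural call was also lost with the largest other list (adjusted exact p = 0.0729) and against all annotated genes (0.113), and its odds ratio was 1.07 among the 500 strongest peaks. Small nuclear and nucleolar RNA genes were called lower at 25 of 177 (odds ratio 0.598, adjusted exact p = 0.0268), with snRNA:7SKa highest at 765. That call was lost without replicates 1 and 3 (adjusted exact p = 0.146 and 0.18) and with windows of 250 and 1000 bp (0.223 and 0.312). It was also lost against promoter-matched draws (adjusted permutation p = 0.898). Under circular shifts the list was higher, with 25 genes against a mean of 5.94 drawn, but these shifts do not keep summits at promoters.

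The other 11 lists were not called. Germline and piRNA genes had a peak in 6 of 18 (tej, stwl, tud and gcl highest), and heat shock and chaperone genes in 5 of 17 (DnaJ-1, Hsp83, Hsp60A and Hsc70-5 highest). Glycolysis genes had one in 2 of 13 (Eno and Pgi), Hox genes in 1 of 7 (abd-A), segmentation genes in 2 of 25 (ems and bcd), and muscle genes in 2 of 22 (Mef2 and Tm1). Gut and malpighian genes had one in 2 of 16 (Vha16-1 and Vha26), and antimicrobial and immune effector genes in 2 of 16 (imd and AttD). No peak was found at 17 fat body and haemocyte genes (adjusted exact p = 0.0512) or 16 chorion and vitelline genes (adjusted exact p = 0.0511). Fat body genes were called lower against promoter-matched draws (adjusted permutation p = 0.0485). Germline and heat shock genes were called higher under circular shifts (adjusted permutation p = 0.002 for both), which do not keep summits at promoters. Against promoter-matched draws neither was called (adjusted permutation p = 0.172 and 0.745). Of the replication-dependent histone genes only 2 were in the background, and neither had a peak. Against all annotated genes the histone list was called lower (adjusted exact p = 1.3e-08).

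**Figure D2:**
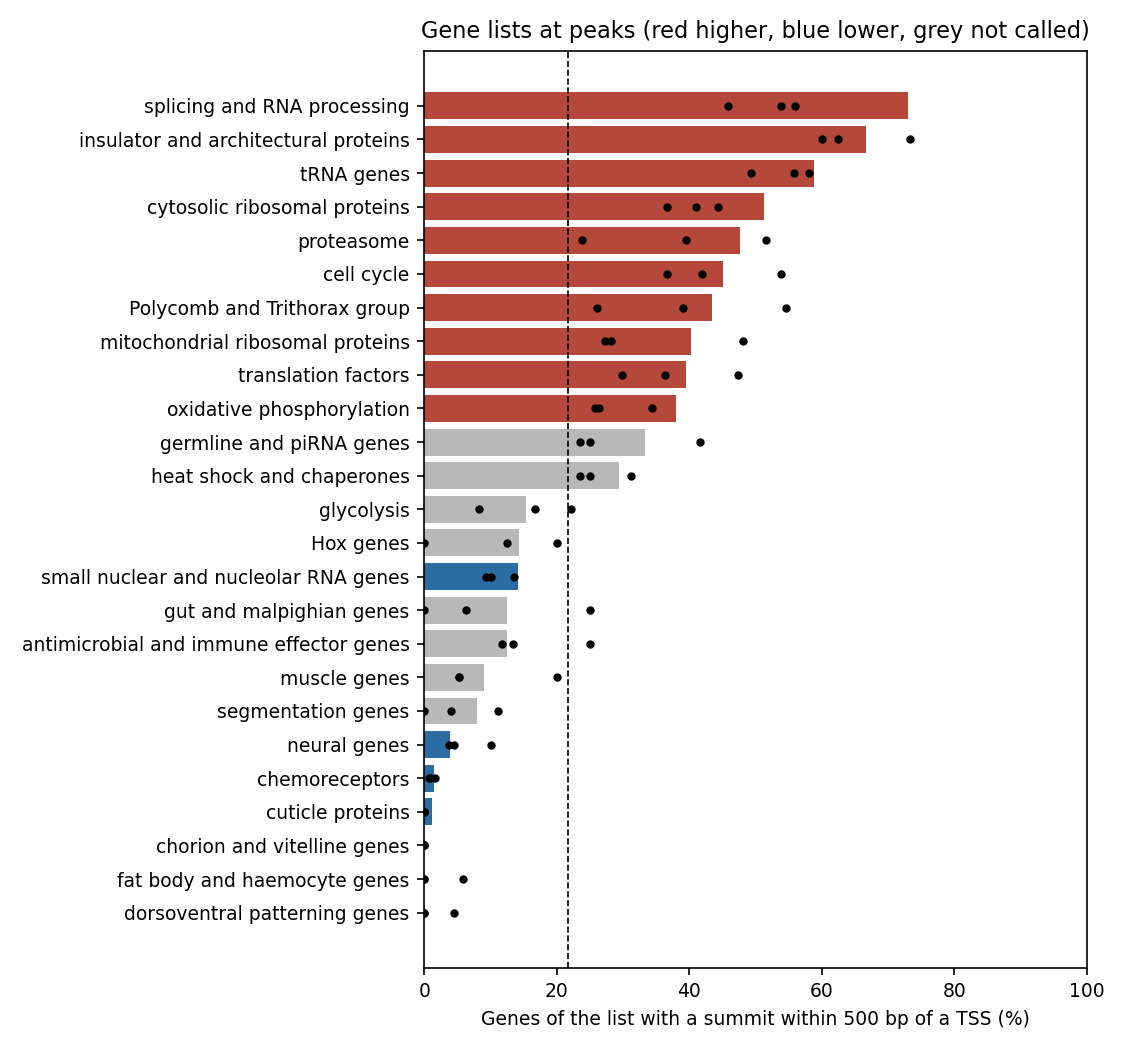
Percent of the background genes of each list with a main-list summit within 500 bp of a TSS (bars; red higher, blue lower, grey not called) and in each of the 3 replicate lists (points). The dashed line is the 21.8% of all background genes, and replication-dependent histones, with 2 background genes, are not drawn.

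The DNA replication-related element (DRE), TATCGATA, was the leading sequence with the overlapping BEAF-32 consensus YATCGATAR. The DRE lay within 100 bp of 715 of 2827 summits, 25.3%, against 1.85% of the matched background (odds ratio 17.9, 15.3 to 21.0). The replicate lists gave 28.5% ± 1.24 (SD, n = 3), against 2.83% in their backgrounds. The BEAF-32 consensus was found at 27.8% against 2.06% (odds ratio 18.2). Both p of Fisher's exact test were below 2.23e-308. The background was matched on promoter class and GC content, but not on distance to the TSS or side of the TSS. A difference in the position of summits within promoters was therefore not separated from these or the other sequence differences. Ohler motif 7, a core promoter word, was at 18.3% of summits against 3.32% (odds ratio 6.51, adjusted exact p = 1.66e-150). The M1BP word GGTCACACT was at 4.67% against 1.29% (3.75, adjusted exact p = 5.23e-25), and the B box of tRNA genes at 1.49% against 0.247% (6.07, adjusted exact p = 6.1e-13). Ohler motif 6, the CTCF core, both the palindromic and the CAGCTG E-box, and the DPE were also higher, with odds ratios of 3.07, 2.28, 1.49, 1.47 and 1.27. The CTCF call had an adjusted exact p of 0.0869 without replicate 1 and 0.0782 without replicate 3, and its odds ratio was 0.860 among the 500 strongest peaks. The DPE was not called without matching (1.04, adjusted exact p = 0.714) or against flanking windows (1.09, 0.473), nor the CAGCTG E-box against flanking windows (1.16, 0.0629). The palindromic E-box had an adjusted exact p of 0.0541 within 50 bp of summits and 0.126 among the 500 strongest peaks, where Ohler motif 6 had 0.136. Without matching, the odds ratios of the DRE, BEAF-32, M1BP, B box and Ohler motif 6 words were 70.9, 54.8, 20.4, 27.2 and 8.97, and against flanking windows 48.2, 36.9, 19.1, 13.3 and 14.2. Among the 500 strongest peaks Ohler motif 7 had 11.9, M1BP 2.14 and the DPE 2.07, and without replicate 3 Ohler motif 6 had 2.03.

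The GATA word was lower, at 1.31% against 2.40% (odds ratio 0.545), as were the TCF (0.447), ribosomal TCT (0.673), CA repeat (0.695), Snail E-box (0.705), GAGA repeat (0.741), STAT92E (0.790) and initiator (0.884) words. The DRE, BEAF-32, Ohler motif 7, M1BP, B box and TCT calls were made under all 9 alternatives. The GATA call was lost within 50 bp (adjusted exact p = 0.0541) and without matching (0.0518), and the TCF call within 50 bp (0.101), against flanking windows (0.153) and among the 500 strongest peaks (0.333). Without replicate 1 the odds ratios of the GATA, TCF and CA repeat words were 0.354, 0.196 and 0.444. Without replicate 3 TCF had 0.226 and the CA repeat 0.452, and without replicate 2 the CA repeat had 0.456. Among the 500 strongest peaks the GATA, CA repeat and GAGA repeat words had 0.322, 0.308 and 0.419. The CA repeat was not called against flanking windows (adjusted exact p = 0.109). The GAGA repeat was not called under 6 of 9 alternatives and STAT92E under 4 of 9. Without replicate 1 the Snail E-box, STAT92E and initiator words had an adjusted exact p of 0.0644, 0.0644 and 0.0869, and without replicate 3 the Snail E-box and initiator words of 0.0546 and 0.0997. Among the 500 strongest peaks the Snail E-box and initiator words had 0.0567 and 0.584. Without matching, the initiator had an odds ratio of 1.01, and with the largest other list the GAGA repeat of 1.02. Zelda, Twist, Su(Hw), TATA box, Grainyhead, Pho, homeodomain and AP-1 words were not called. Without matching, the TATA box and homeodomain words were higher, with odds ratios of 1.58 and 1.35. Among the peaks found in both other replicate lists, whichever replicate was left out, the TATA box was called lower, at odds ratios of 0.814, 0.802 and 0.808, and Pho was lower without replicate 3, at 0.584, and among the 500 strongest peaks, at 0.411. The Twist word was lower without matching and against flanking windows (0.722 and 0.715), Zelda against flanking windows (0.499) and the homeodomain word within 50 bp (0.774). The DRE share was 7.42% (5.40 to 9.90%) in the lowest quintile of signal values and 34.8% (30.9 to 38.9%) in the highest, and that of Ohler motif 7 was 6.71% and 28.1%. Among the 25 strongest peaks, 4 carried the DRE and 6 Ohler motif 7. All 20 leading 8-mers of arms 2L and 2R were called on the held-out arms, and each contained ATCG or CGAT. ATCGATAG was at 26.8% of 1701 held-out summits against 112 of 7470 background peaks (odds ratio 24.0, adjusted exact p = 9.29e-244).

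**Figure D3:**
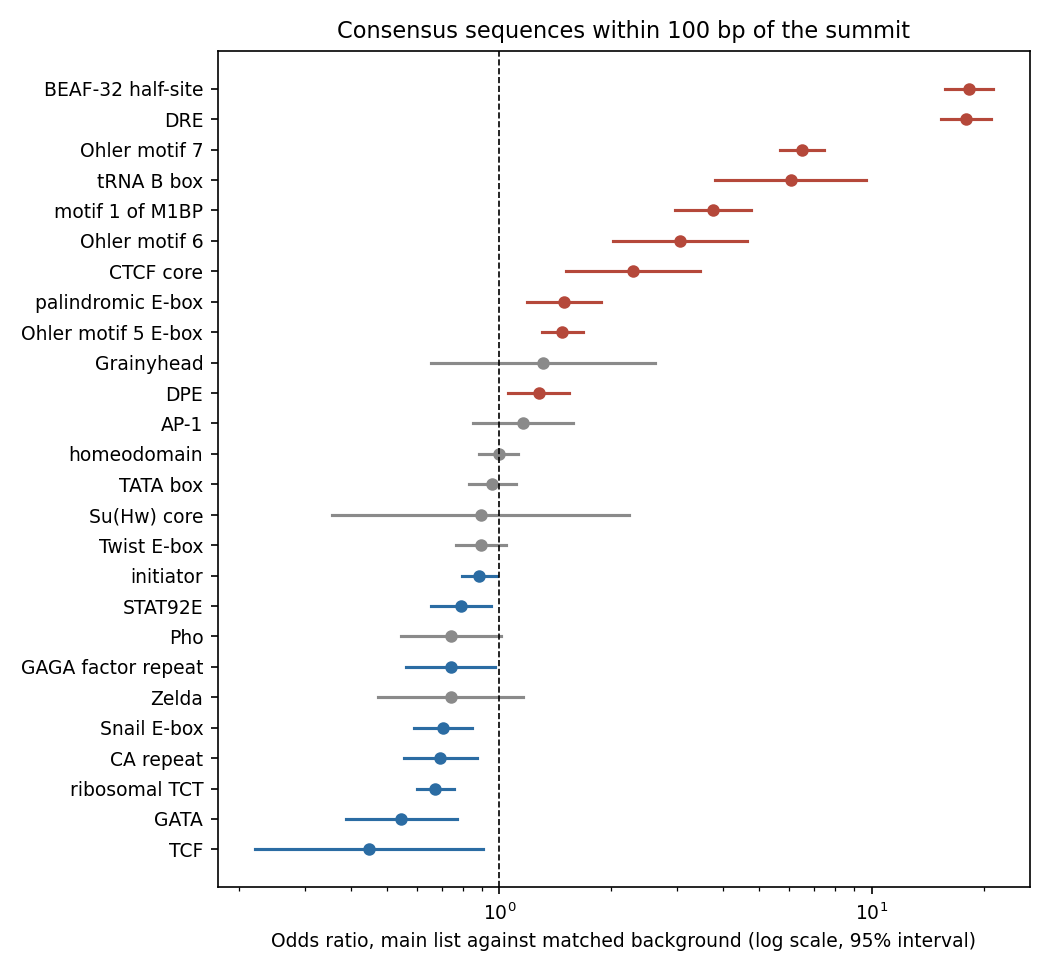
Odds ratio of each of the 26 consensus sequences within 100 bp of main-list summits against the matched background, on a log axis, with 95% intervals (red higher, blue lower, grey not called). The BEAF-32 consensus and the DRE stand highest, at 18.2 and 17.9.

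**Figure D4:**
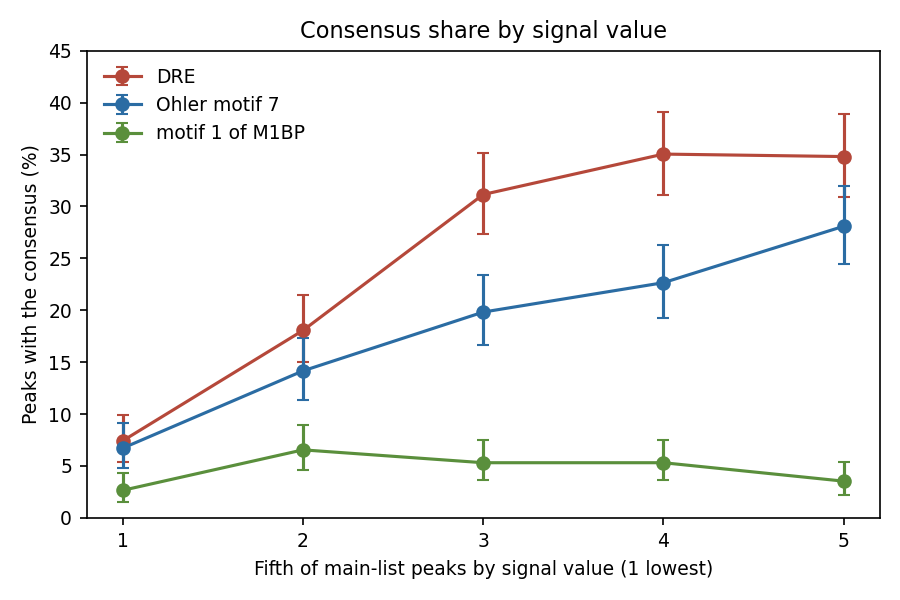
Percent of main-list peaks with the DRE, Ohler motif 7 or the M1BP word in each quintile of peaks by signal value, with exact 95% intervals. The DRE share is 7.42% in the lowest quintile and 34.8% in the highest.

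Peaks were not spread evenly over the arms. Against below-threshold peaks, 2R held more (21.1% against 18.8%, odds ratio 1.16, adjusted exact p = 0.00512), as did X (19.9% against 17.9%, 1.14, adjusted exact p = 0.00899). Arm 3R held fewer (21.3% against 25.3%, 0.802, adjusted exact p = 4.13e-06), and Y held 0 of 2827, which allows a share of up to 0.106% at a limit of 3 peaks, against 0.568%. Arms 2L and 3L were not called. Among the peaks found in both other replicate lists, whichever replicate was left out, 3L was lower, at odds ratios of 0.859, 0.816 and 0.803. Against arm length, 2L was higher (1.12) and 3L lower (0.880). Chromosome 4 held 15 peaks, 0.531% against 0.237% (odds ratio 2.32, adjusted exact p = 0.00899), but against arm length it was lower, with an odds ratio of 0.557 and 11.1 peaks per Mb against 20.6 over all arms. The X call was turned with the largest other list (odds ratio 0.939), and none of the 7 arms was called among the 500 strongest peaks.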

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

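The values here lie outside the comparisons of the report and were looked at only after its results were seen. There were 96 peaks past the authors' threshold in the ranked list that were not in the main list. Of the 74 on the arms, 53 were at promoters, 71.6%, and 11 carried the DRE, 14.9%. The highest signal values among them were at osa, 1221, kibra, 1124, and Bicra, 892, which were chosen after their values were seen. The thresholded lists have 1 more parent file whose content is not stated, and no explanation was tested. A further 57 main-list peaks lay on 52 unplaced sequences, with a median signal value of 110. The 2 series lists not used in the report held 669 peaks on the arms that overlap no main-list peak, of which 380 were at promoters, 56.8%.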

How the results depend on the processing

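The single-peak-per-cluster, remaining-pair and promoter-matched alternatives were chosen after seeing the data. The promoter share stayed higher than background under all 10 alternatives, from 72.8 to 97.0%, and the pairwise overlap under all 7, from 71.8 to 86.9%. In each of 9 alternatives the 20 leading 8-mers chosen anew were all called, and 16 to 18 of them were among the 20 of the main list. The share of peaks in all 3 replicates was 40.1% with the largest other list, 99.0% among the 500 strongest, 34.6% with reciprocal overlap of 50% and 47.2% with summits within 100 bp; it was 56.1 to 63.1% when a replicate was left out and only 2 had to hold the peak. The median summit SD was 13.4 bp among the 500 strongest and 13.4 to 16.3 bp over 2 replicates. With the 500 strongest peaks, 0 arms, 5 gene lists and 11 consensus sequences were called, against 5, 15 and 18; fewer peaks were tested. Keeping only the peaks found in both other replicate lists, with each replicate left out, gave 8 to 11 gene lists from 1587 to 1783 peaks; the filter and the replicate were not separated. Against promoter-matched draws, 14 of the 15 gene list calls remained.

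Odds ratios or ratios that changed side of 1 follow. The cause was not tested, but for a list without any peak a ratio above 1 comes only from the constant added to each cell. Largest other list: 3L 1.00, X 0.939, gut 1.04, GAGA repeat 1.02. The 500 strongest: 2L 0.997, histones 3.63, glycolysis 2.18, Hox 1.21, neural 1.07, insulator 0.584, CTCF 0.860, Grainyhead 0.650, homeodomain 1.00. No histone or Hox gene had a peak among these 500, so 3.63 and 1.21 show no enrichment. No insulator gene had one either, so 0.584 rests on the same constant and shows no depletion. Leaving out a replicate: 2L 0.975 to 1.01, histones 1.07 to 1.24, antimicrobial 0.926 to 1.07, Grainyhead 0.927 to 1.27, Su(Hw) 0.703 to 1.44, homeodomain 0.943 to 1.00. Windows: histones 1.03 at 250 bp, Grainyhead 0.965 at 50 bp. Histone genes had no peak in the main list, so their ratios with a replicate left out and at 250 bp show no enrichment either. All genes as background: glycolysis 1.06. Circular shifts: small RNA 3.96, glycolysis 2.67, Hox 1.83, segmentation 1.95, muscle 1.81, gut 2.46, antimicrobial 2.29. Arm length: chromosome 4 0.557. Unmatched: TATA box 1.58, initiator 1.01, homeodomain 1.35. Flanking windows: Su(Hw) 1.29, TATA box 1.24, initiator 1.03, Pho 1.36, homeodomain 1.37.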

Other observations

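The tests of the INE-1 sequence words, the weak peaks and the tRNA gene peaks were chosen after the results they rest on were seen, as were the counts of divergent promoters. Divergent promoters were common: 980 of 2340 promoter summits, 41.9%, had TSSs of opposite strands pointing away from each other within 500 bp, against 9.85% of below-threshold promoter summits (odds ratio 6.60, p = 3.12e-302 by Fisher's exact test). Distance to the TSS and side of the TSS were not matched. A difference in the position of summits within promoters was therefore not separated from this one. Of the strongest peaks away from promoters, the first was in an intron of org-1 and the second in an intron of Dscam1, a cell surface receptor gene (2R, 7377176 to 7377496, signal value 791). The next 3, nearest to ArgRS, Pld and ed, were intergenic, and each summit lay inside a copy of INE-1, a short transposable element.

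INE-1 elements held 78 of 2827 main-list summits, 2.76%, against 0.330% of below-threshold peaks (odds ratio 8.61, 6.76 to 11.0), and 2.51% ± 0.422 of the replicate lists (SD, n = 3). Of the 78 peaks, 28 were found in all 3 replicate lists and 12 in none, against 1509 and 436 of the 2827. Reads shared between copies would be needed where the sequence around the summit is repeated, but the median share of 50-base words that occur once in the genome was 100% (bootstrap interval 100 to 100%). Only exact matches were counted, so reads placed with mismatches between similar copies were not tested. The read length is not given, and shorter reads were not tested either. The 8-mer that best separated elements with and without a summit on 2L and 2R, CAGATACC, was then tested on the other arms except Y. There 37 of 381 elements with it held a summit and 11 of 955 without it (odds ratio 8.94, 4.57 to 17.5). A second test kept elements at least as long as the lower quartile of those with the 8-mer on 2L and 2R. It kept 326 of the 381 and 796 of the 955, so length was controlled only loosely, and its odds ratio was 14.3 (6.14 to 33.5). Both odds ratios argue against the element whatever its sequence. The longer word CTATCAGATAC, found at these peaks, had a peak at 80 of 526 copies inside INE-1, 15.2%, and at 34 of 401 outside annotated transposable elements, 8.48%, so most copies had none, sequence around the word may matter too, and no biological explanation was tested.

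Of the main-list peaks, 58 had a signal value under 10, and all 58 lay within 1000 bp of a main-list peak with a value over 50, against 2.40% of below-threshold peaks; 46 had the highest score, 1000, and 50 overlapped a peak of at least 1 replicate list. A candidate explanation is that these are parts of a neighbouring strong peak called separately. The DRE was at 1 of the 58 and at 714 of the other 2769 (odds ratio 0.075, 0.0148 to 0.380), which met the prediction of that explanation as first set. The DRE share falls with the signal value, however, so a comparison with the other peaks of the lowest quintile was made a further requirement after that result was seen, and its odds ratio was 0.294 (0.0563 to 1.53, p = 0.109 by Fisher's exact test). Separate weak sites and parts of strong peaks therefore cannot be told apart by the DRE, since the interval within the quintile includes 1.

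Peaks with a tRNA gene TSS within 500 bp differed in sequence from the other promoter peaks. The DRE was at 1 of them, 0.813%, against 30.2% (odds ratio 0.0283, 0.00563 to 0.142), which argues against DRE-linked binding of the same kind at tRNA genes. The B box consensus was at 40 of them, and 82 were found in all 3 replicates. Their median share of unique 50-base words was 82.2%, against 100% at other promoter peaks, so reads shared between tRNA copies stay open as an untested contribution. Precipitation at strongly transcribed genes whatever the tagged protein also stays open, since control precipitations were not analysed here.

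A last hypothesis was that summits may follow the TSS and not the DRE. Among 147 promoter peaks with a DRE 100 to 500 bp from the nearest TSS, the summit was nearer to the DRE in 77, 52.4% (exact interval 44.0 to 60.7%). The median distances were 104 bp to the DRE and 103 bp to the TSS, and the interval includes 50%, so the test did not decide between them.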
